A study of Homo sapiens with 36 samples.

How the data were processed

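MicroRNAs were measured on single-colour Exiqon microarrays (generation 6, probe content of miRBase 17) in HepG2 cells exposed to cyclosporin A (CsA) at 3 or 20 µM or to DMSO for 12, 24, 48 or 72 h. Per the labels, cells were treated at 80 % confluence in 0.5 % DMSO, total RNA was isolated with a miRNeasy kit, samples had a RIN above 8, and 1 µg of RNA per array was labelled with Hy3. The 36 arrays fall into 12 groups of 3 biological replicates, taken from the labels. Per the file headers, each array was read with Agilent Feature Extraction 10.7.1.1, and the processed signal is an intensity in scanner units, corrected for background within the array and not normalized between arrays. The mean pixel signal and the local background of each spot are intensities as well, per the file headers, and the quality marks of each spot are other values of 0 or 1 set by the same program. The authors also deposited values of 1346 probes, which were read here as log2, because each column correlated across probes with the log2 scanner signal of its array (r from 0.655 to 0.996). Column medians of that deposited log2 table lay between 5.3 and 5.39, so its arrays had been made alike, and the normalization behind it is not given in the sources used here. Neither its scale nor its centring is stated, and the table served only as an alternative.

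All main values were computed from the scanner files in R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8). Each array was scaled to its 75th percentile over the 1893 non-control probes detected on all 36 arrays and brought back to the geometric mean of these percentiles. Signals at or below 0 were set, after scaling, to the lowest positive value of the array, and the spots of a probe were averaged on the log2 scale without spots marked as non-uniform or population outliers (2.32 % of spots). A probe counted as detected on an array when over 0.5 of its spots were well above background. Tested were the 1264 of 1275 probes naming a human miRNA that were detected on all 3 arrays of at least 1 group, and the other 11 were left out. The probe of the highest mean was to stand for a full probe name found on several, which applied to 0 names. A miRNA such as miR-378 can thus be named by more than 1 tested probe. Of the probes that name a human miRNA, 61 carry the maker's own miRPlus names and 13 name more than 1 human miRNA. Names follow the array, in which a star marks the minor arm, and no genome was used, so positions are not given. Related miRNAs can differ by a few bases, so the probes of a family are not independent of each other.

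A mean per group was fitted to all 36 arrays with limma (lmFit, contrasts.fit, eBayes, 24 residual degrees of freedom, two-sided), and 13 contrasts were tested. These were each dose against DMSO at each time, each dose against DMSO averaged over the 4 times, 20 against 3 µM averaged over the times, DMSO at 72 against 12 h, and the effect of 20 µM at 72 h minus that at 12 h. P-values were adjusted by Benjamini-Hochberg over the human probes tested in a contrast, with a threshold of 0.05. The 20 lists of miRNAs were fixed beforehand and tested with camera of limma at a preset correlation of 0.01, adjusted over the lists, beside the same test with an estimated correlation. Probes of other classes were fitted with the same model and adjusted within their class. The lists cover hepatocyte-enriched miRNAs, p53, endoplasmic reticulum (ER) stress, hypoxia, lipid and bile acid regulation, inflammation, and fibrosis with epithelial-mesenchymal transition. Others hold the miR-17-92, let-7, miR-30, miR-200, miR-15, miR-23/27/24 and miR-181 families (miR-15 with miR-16 and miR-503), the chromosome 19 and 14q32 clusters, entries that overlap other small RNAs, and markers of blood, of endothelium and fibroblast, and of muscle and neuron. The entries that overlap other small RNAs (fragments of tRNA, U2, vault and Y RNA) were listed as a sign of RNA breakdown.

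Lists, contrasts, filters and the miRNAs to be named were chosen before the data were examined. Named were, among miRNAs past the threshold, the 12 largest rises and the 12 largest falls of 20 µM averaged over times that had the same sign at all 4 times. For 3 µM and for 20 against 3 µM averaged over times the numbers were 6 and 6, for each time of 20 µM 4 and 4, and for every other contrast 3 and 3. Where none passed, the 3 with the smallest p were taken. Up to 4 members of each list with the smallest p at 20 µM averaged over times could be named too, as could miR-122, miR-34a, miR-21, miR-210, miR-33a and let-7a in every case. Any other miRNA named was chosen after its values were seen, and the text says so.

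Alternatives set beforehand were normexp background correction of the mean signal with an offset of 50, the 75th percentile over all non-control probes, quantile normalization, no filter, a stricter filter (detected on all 36 arrays, 1043 probes), a fit of the compared groups alone, the replicate number as a block, the scan day as a block, the authors' values, and leaving out each array in turn. Chosen after seeing the data were a filter on the 95th percentile of the 28 negative control spots (236 probes), scaling on the probes above that percentile, scaling on the spike control spots, and a fit without 2 arrays at 24 h that stood apart. Each of the 12 scan days held 1 DMSO, 1 3 µM and 1 20 µM array of a single time. Doses could thus be compared within a scan day, whereas times could not. Other splits of the arrays were counted in full up to 100 and otherwise drawn.

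The procedure was tested on simulated data with 1264 probes, of which 200 were changed. For the mean over times it called 87 % of probes changed by 1 log2 unit and 99 % of those changed by 2 units, with 4.62 % false among the calls, and at a single time 50 % and 88 %, with 4.83 % false. When the scaling step was simulated too, unchanged probes moved by −0.12 and the false share rose to 15.4 %, since the changed probes shift the percentile. The changed probes were drawn at random over all signal levels, with as many rises as falls of each size. The real changes were not balanced in this way, so these 2 values need not give the size of the shift in the real arrays. In the same simulation no probe was changed between 3 µM and DMSO, and there 0 of 1264 were called for the mean over times. The noise was drawn independently for each probe, so the false shares need not hold for the real arrays, whose probes are not independent. With shifts between scan days added, the fit of group means called 86 % and 98 % with 1.08 % false, and the fit with the scan day as a block 87 % and 99 % with 4.62 % false. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.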

Results

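The miRNAs of HepG2 cells, a human hepatocellular carcinoma line, were measured after exposure to cyclosporin A (CsA), an immunosuppressant that inhibits calcineurin, or to the solvent DMSO. CsA was given at 3 or 20 µM for 12, 24, 48 or 72 h, with 3 biological replicates in each of the 12 groups and 1 array per sample. The labels do not say whether the replicates came from separate cultures, so every p-value rests on the spread between these samples, whatever its source. Of 1264 human probes tested, 187 had a mean signal above the 95th percentile of the negative control spots (log2 6.10) and 1077 lay at or below it. Wherever a signal is said to lie above or below the negative controls, that percentile is meant, not their typical level. It was taken over the single negative control spots of all 36 arrays together, while the probe values set against it are means. Replicate 1 of 3 µM at 24 h entered it too, with an own 95th percentile of 1020 scanner units against a median of 56.4 per array. The 75th percentile of the signal ranged from 35.3 to 84.6 scanner units per array. The number of arrays limits the precision, and the median SE of a log2 change was 0.17 for a mean over times (12 arrays against 12) and 0.34 for a single time (3 against 3). At 24 h, 2 arrays stood apart. Replicate 1 of 3 µM had a median r of 0.0134 with the other 35 arrays, and DMSO replicate 3 had 785 spots not found, against a median of 12.5. In the other 10 groups the lowest correlation between replicates, across probes that are not independent replicates, lay between 0.74 and 0.946. The first principal component carried 34.7 % of the variance. On it the DMSO arrays ran from −25.8 to 8.65 and the 20 µM arrays from −3.68 to 15. The median r with the other 35 arrays ran from 0.38 (next lowest 0.771) to 0.918 with DMSO. At 20 µM it ran from 0.874 to 0.926. Whether this difference between the doses stems from the arrays or from the treatment was not tested.

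The main comparison asked which miRNAs differed between 20 µM CsA and DMSO over all 4 times. The largest rise was that of miR-1290, by 3.58 ± 0.70 log2 units (SE here and in what follows), or 11.9-fold (adjusted p = 0.00132, 12 arrays against 12). It was higher under CsA on 12 of 12 scan days. In the groups at 72 h, miR-1290 went from a scaled log2 signal of 9.37 ± 2.63 (SD, n = 3) with DMSO to 14.59 ± 0.52 with 20 µM. miR-1246, which overlaps the U2 small nuclear RNA, rose 8.48-fold (3.08 ± 0.66, adjusted p = 0.00344, 12 of 12 days). miR-4306 rose 9.27-fold (3.21 ± 0.57, adjusted p = 0.000487, 11 days), miR-4285 by 3.13 ± 0.47 log2 units (adjusted p = 8.7e-05, 12 days) and miR-3611 by 3.00 ± 0.50 (adjusted p = 0.000227, 12 days). The miRNA miR-299-5p of the 14q32 cluster rose 6.56-fold (2.71 ± 0.43, adjusted p = 0.000157), and miR-1908, from an intron of FADS1, rose 5.56-fold (2.47 ± 0.39, adjusted p = 0.000146). The minor arm miR-149* rose 5.14-fold (2.36 ± 0.35, adjusted p = 7.65e-05), and all 3 did so on 12 of 12 days. Next to these, miR-711 (2.82), miR-3915 (2.69) and miR-3202 (2.56) rose, with adjusted p between 0.00071 and 0.000955. No fold is given for miR-4285, miR-3611, miR-711, miR-3915 and miR-3202. Their mean with DMSO, from 4.73 for miR-711 to 6.01 for miR-4285, lay below the 95th percentile of the negative controls (6.10), though the scanner marked each as well above background on 12 of 12 DMSO arrays. miR-1275 rose 5.8-fold (2.54 ± 0.62, adjusted p = 0.0102, 11 days). It lost its call with the authors' values (1.22) and with quantile normalization (adjusted p = 0.14, the highest over its alternatives, from 0.000296). The other 11 of these 12 rises passed without any single array and under every alternative that tested them. The stricter filter left out miR-1290 and miR-299-5p. The size of the rises, and so the folds, depended on the setting. Over all alternatives the log2 change ran from 2.15 to 3.92 for miR-1290 and from 2.02 to 3.31 for miR-1246. It ran from 2.35 to 3.41 for miR-4306, 1.85 to 2.88 for miR-299-5p, 1.61 to 2.65 for miR-1908 and 1.501 to 2.486 for miR-149*.

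**Figure D1:**
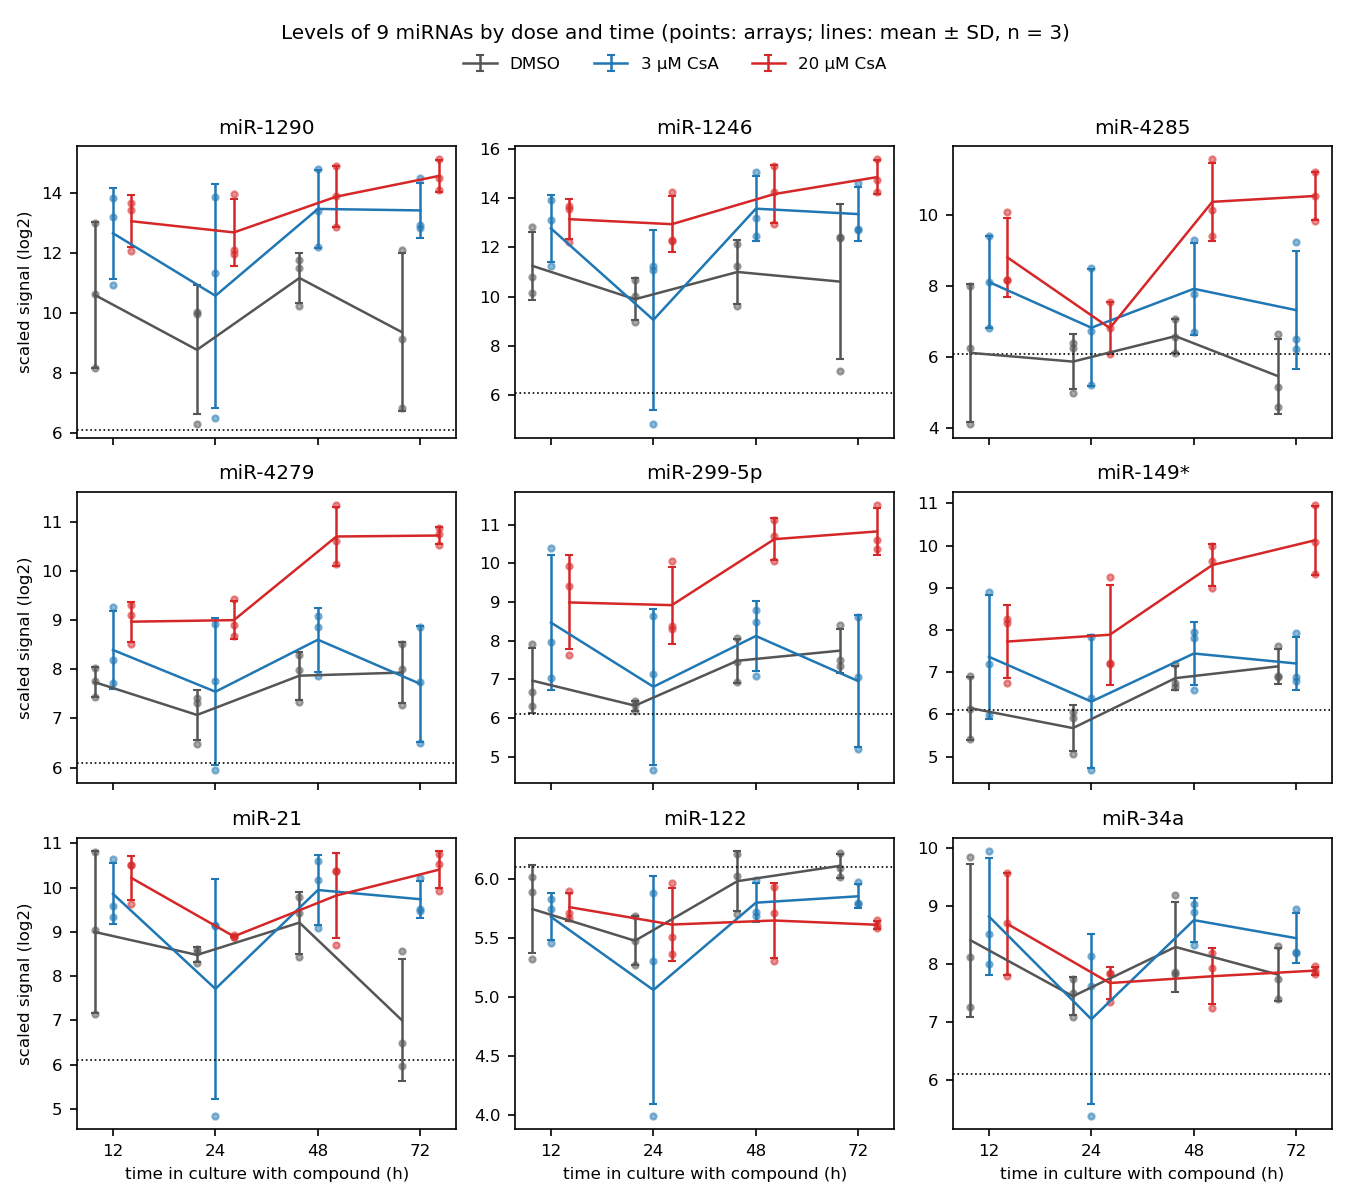
Scaled log2 signal (y axis) of 9 miRNAs against time (x axis, 12 to 72 h) with DMSO (grey), 3 µM CsA (blue) and 20 µM CsA (red), where points are single arrays, lines and bars the mean ± SD of 3 arrays, and the dotted line the 95th percentile of the negative controls (6.10). At 72 h miR-4285 stood at 5.46 ± 1.06 with DMSO and 10.54 ± 0.69 with 20 µM, and miR-4279 at 7.93 ± 0.62 and 10.72 ± 0.17.

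In total 93 of 1264 miRNAs passed in limma at 20 µM averaged over times, 64 higher and 29 lower, with the smallest adjusted p (2.59e-05) for miR-4279 (2.19 ± 0.28, 12 of 12 days). The mean signal over 36 arrays of 41 of the risen and 0 of the fallen miRNAs lay above the negative controls, and with DMSO alone that of 21 of the risen did. The median of all probes stood at −0.15, and against it the fallen probes had a median of −0.30. With the scan day as a block the count was 236 (98 higher, 138 lower), which included all 93. The split of 64 against 29 was 67 against 21 with the percentile over all non-control probes, 46 against 2 with normexp, 63 against 14 in the authors' values, 77 against 68 with the compared groups alone, and 34 against 0 when scaled on the spike spots (median of all probes −0.31). Without the 2 arrays at 24 h that stood apart it was 80 against 38. Scaled on the probes above the negative controls the split was 24 against 1063, with the median of all probes at −1.01. Scaling on another set of probes shifts all probes of an array by 1 common amount on the log2 scale. All log2 changes thus moved down together under this scaling. A sign that turned under it does not set a miRNA or list apart from the other probes. Leaving out 1 array gave 141 without replicate 2 of DMSO at 24 h, 61 and 56 without replicates 3 and 2 of DMSO at 48 h. It gave 60 without replicate 1 of DMSO at 12 h and 56 without replicate 1 of DMSO at 72 h. For 20 µM it gave 60, 55 and 51 without replicate 3 at 12 h, replicate 2 at 24 h and replicate 3 at 72 h.

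**Figure D2:**
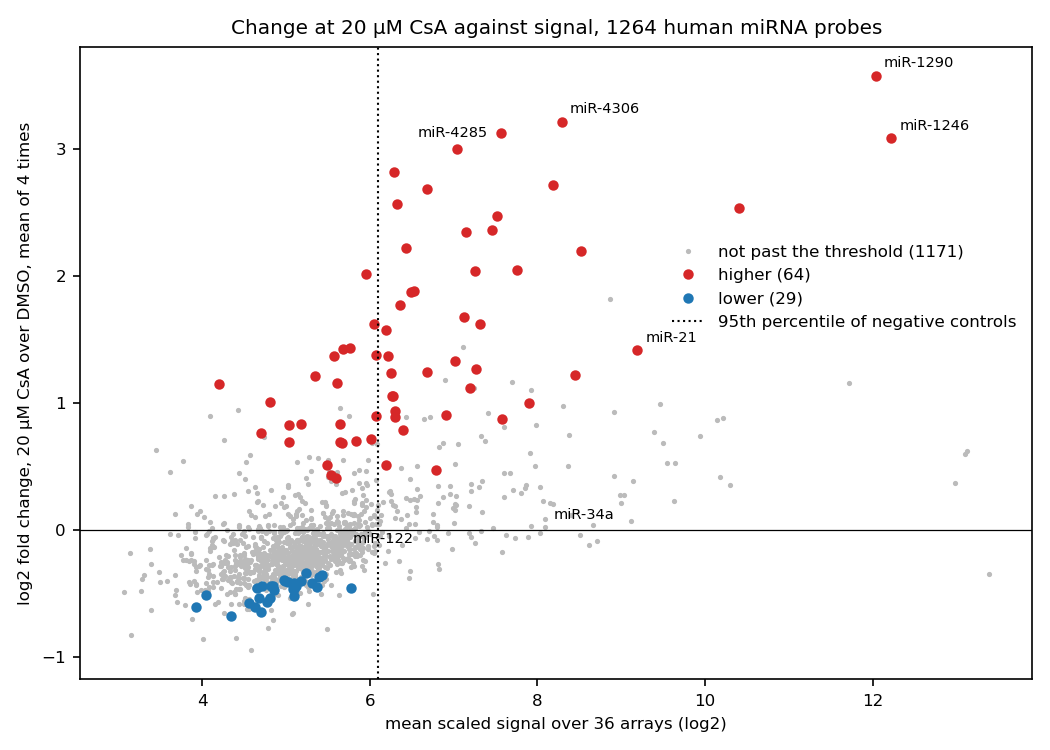
Log2 fold change of 20 µM CsA against DMSO averaged over times (y axis) against the mean scaled log2 signal over 36 arrays (x axis) for 1264 miRNAs, of which 64 rose (red) and 29 fell (blue), with the others in grey. Of the red points 41 lie above the negative control percentile of 6.10 and of the blue points 0.

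Among the falls, miR-519c-3p of the chromosome 19 cluster, which is expressed mainly in placenta, fell by 0.57 ± 0.14 log2 units (adjusted p = 0.00714, lower on 11 of 12 days). The miRNA miR-3674 fell by 0.54 ± 0.12 (adjusted p = 0.00612), and miR-4262, with the largest fall, by 0.68 ± 0.20 (adjusted p = 0.035). The other 9 of the 12 largest falls, those of miR-518c, miR-2682, miR-875-5p, miR-15a*, miR-148b*, miR-3140-3p, miR-549, miR-544b and miR-3681, lay between −0.65 and −0.46 with adjusted p between 0.0307 and 0.0497. All 12 had a mean signal at or below the negative controls. None of the 12 passed with normexp or when scaled on the spike spots. Over their alternatives the adjusted p of miR-519c-3p went from 0.00309 to 0.166, that of miR-3674 from 0.000942 to 0.2, and that of miR-4262 from 0.0033 to 0.415. The calls of miR-519c-3p and miR-3674 held without any single array, while each of the others was lost without any 1 of 10 to 19 of the 24 arrays.

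The liver's most abundant miRNA, miR-122, had a log2 change of −0.17 ± 0.15 (adjusted p = 0.424) and lay below the negative controls. A rise of 1.87 ± 0.37 (adjusted p = 0.00133, 12 of 12 days) was measured for miR-675, which is processed from the H19 RNA. The mean of miR-675 with DMSO, 5.58, lay below that percentile as well. The miRNA miR-21, an abundant miRNA of many tumours, rose 2.66-fold (1.41 ± 0.42, adjusted p = 0.0394, 10 of 12 days). The call of miR-21 was lost with normexp, with quantile normalization, in the authors' values and when scaled on the probes above the negative controls, and without any 1 of 15 of the 24 arrays (adjusted p from 0.00908 to 0.266). Its minor arm miR-21* rose by 1.24 ± 0.26 (adjusted p = 0.00299, 12 days), and passed without any single array, but not when scaled on the probes above the negative controls (adjusted p = 0.155, the highest, from 0.000688). For miR-34a, a target of p53, the change was 0.02 ± 0.30 (adjusted p = 0.973). It turned to −0.84 (adjusted p = 0.0033) when scaled on the probes above the negative controls, and fell after quantile normalization too (adjusted p = 0.0469). The hypoxia-induced miR-210 had −0.04 ± 0.36 (adjusted p = 0.951), miR-33a, from an intron of SREBF2, −0.38 ± 0.21 (adjusted p = 0.227), and let-7a −0.17 ± 0.30 (adjusted p = 0.726). Under alternatives miR-122, miR-210 and let-7a passed as falls in 1 each and miR-33a in 3. Their lowest changes were −1.03, −0.90, −1.03 and −1.24 (lowest adjusted p = 0.0033, 0.00363, 0.00454 and 0.00199). The scaling on the probes above the negative controls moved them down with all other probes.

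Among the lists, 16 entries that overlap tRNA, U2 and other small RNAs had the smallest p at 20 µM averaged over times, with a median log2 change of 0.37 that turned to −0.50 when scaled on the probes above the negative controls. Besides miR-1290 and miR-1246, miR-3687 (1.37 ± 0.23, adjusted p = 0.000212, 11 of 12 days) and miR-3648 (1.62 ± 0.31, adjusted p = 0.00106, 12 days) rose, though neither of these passed when scaled on the probes above the negative controls (adjusted p = 0.0633 each, the highest, from 6.92e-05 and 0.000299). Of the 16, 5 passed over all miRNAs and 6 adjusted over the list alone. Camera gave an adjusted p of 8e-07, and an adjusted p of 0.314 with an estimated correlation. The day medians ran from −0.03 to 1.28 and lay above 0 on 10 of 12 scan days, with an adjusted p of 2.16e-06 with the scan day as a block. Its alternatives gave adjusted p from 5.85e-09 to 0.399, and the call was lost with quantile normalization and with the negative control filter. The list was fixed beforehand as a sign of RNA breakdown, which was not tested as a cause.

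In the miR-23/27/24 clusters (10 probes), miR-23a rose 2.32-fold (1.22 ± 0.33, adjusted p = 0.0224, 12 of 12 days), while miR-27a (0.55 ± 0.19, adjusted p = 0.0723), miR-27b (1.16 ± 0.41, adjusted p = 0.0812) and miR-24 (0.97 ± 0.42, adjusted p = 0.141) did not pass over all miRNAs. Adjusted over the list alone 3 of the 10 were higher, and with the scan day as a block miR-27a and miR-27b passed too. The call of miR-23a was lost with normexp, quantile normalization, the authors' values and scaling on the probes above the negative controls, and without replicate 1 of DMSO at 12 h, replicate 2 of DMSO at 48 h or replicate 1 of DMSO at 72 h (adjusted p from 0.00476 to 0.421). The median of the clusters was 0.37, and −0.49 when scaled on the probes above the negative controls (camera adjusted p = 0.0431, and adjusted p = 0.878 with an estimated correlation). The day medians ran from −0.31 to 0.90, above 0 on 9 of 12 days, and the adjusted p with the scan day as a block was 0.0325.

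The 19 probes of the miR-17-92 clusters, which are often amplified in tumours, held miR-25* (0.68 ± 0.22, adjusted p = 0.0626, 11 of 12 days), miR-92a (0.92 ± 0.39, adjusted p = 0.131, 8 days) and miR-20b (0.65 ± 0.38, adjusted p = 0.249, 10 days). None of the 19 passed with the main settings, over all miRNAs or adjusted over the list alone, and 15 had a positive estimate. Under alternatives miR-25* passed in 8 (lowest adjusted p = 0.0224), and miR-92a and miR-20b in 1 each (0.0232 and 0.0354). For the list as a whole the main settings and the alternatives follow. The median of the 19 was 0.23, which turned to −0.63 when scaled on the probes above the negative controls and below 0 with quantile normalization, and whose test turned downward with the negative control filter (camera adjusted p = 0.0217, and adjusted p = 0.878 with an estimated correlation). The fibrosis list (15 probes, 12 of them also in another list) had miR-21 and miR-21* as its 2 rises, also when adjusted over the list alone, beside miR-29b (1.44 ± 0.56, adjusted p = 0.103, 10 days, past the threshold with the scan day as a block). Its median of 0.19 turned to −0.67 when scaled on the probes above the negative controls (camera adjusted p = 0.0431, and adjusted p = 0.878 with an estimated correlation). Day medians ran from −0.57 to 1.26 for the miR-17-92 clusters, above 0 on 6 of 12 days, and from −0.04 to 0.73 for the fibrosis list, above 0 on 10 days. With the scan day as a block the adjusted p was 0.0172 and 0.0264. The call of the miR-17-92 clusters was lost without replicates 1, 3, 2 or 1 of DMSO at 12, 24, 48 or 72 h or replicate 3 of 20 µM at 12 h (camera adjusted p from 0.00276 to 0.863 over all alternatives). Those of the fibrosis list (from 0.0116 to 0.471) and the miR-23/27/24 clusters (from 0.00649 to 0.863) were lost without any 1 of 15 of the 24 arrays, and with the stricter filter. All 3 calls were also lost with normexp, with quantile normalization, in the authors' values and when scaled on the probes above the negative controls. Without the 2 arrays that stood apart, each of these 3 lists had an adjusted p of 0.0513.

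**Figure D3:**
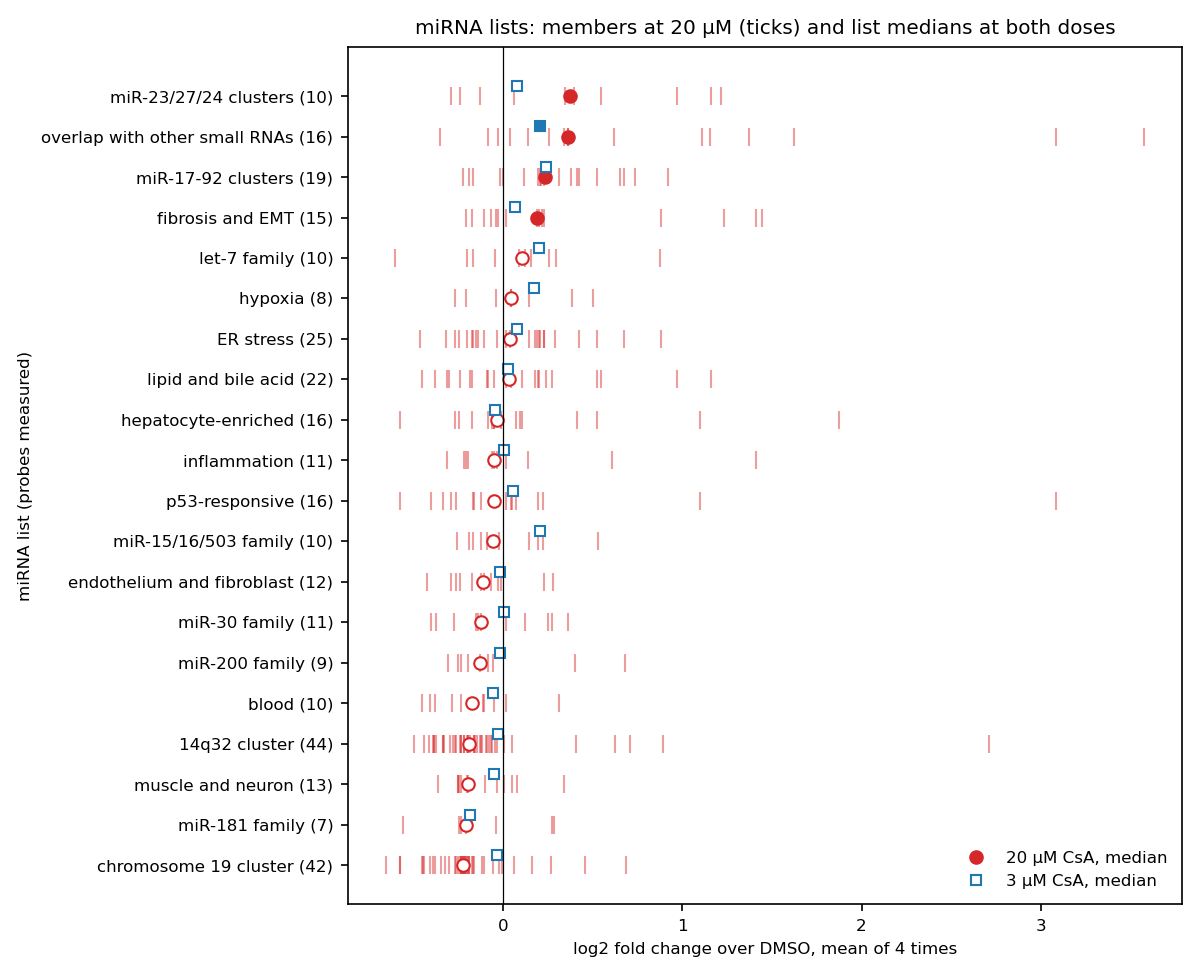
Log2 fold change against DMSO averaged over times (x axis) of the members of 20 lists (y axis), with ticks for members at 20 µM, circles for list medians at 20 µM and squares for those at 3 µM, filled where the camera adjusted p with the preset correlation was under 0.05. The 4 filled circles lie between 0.19 and 0.37, and scaled on the probes above the negative controls the same 4 medians lay between −0.67 and −0.49. Under that scaling the changes of all probes moved down by the same amount.

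No other list passed at 20 µM averaged over times, and the adjusted p with an estimated correlation was 0.878 for each. In the hepatocyte-enriched list (16 probes, median −0.03, camera adjusted p = 0.342) miR-675 rose, over all miRNAs and adjusted over the list alone, and miR-215 had −0.57 ± 0.30 (adjusted p = 0.195). The p53 list (16, −0.05, 0.734) held 1 rise by either count, that of miR-1246, beside miR-605 (−0.40 ± 0.14, adjusted p = 0.0771). Under 5 alternatives miR-605 passed as a fall (lowest adjusted p = 0.0033). In the let-7 family (10, 0.11, 0.342) let-7e rose by 0.87 ± 0.26 (adjusted p = 0.0362, 11 of 12 days), a change of 0.01 when scaled on the probes above the negative controls. Adjusted over the list alone 1 member was higher and 1 lower. The miR-30 family (11, −0.12, 0.791) held 1 fall by either count, that of miR-30d* (−0.37 ± 0.11, adjusted p = 0.0427, lower on 12 of 12 days). The chromosome 19 cluster (42, −0.22, 0.128) held 2 falls by either count, miR-519c-3p and miR-518c, and 1 rise. That rise, of miR-525-5p (0.69 ± 0.19, adjusted p = 0.0227, 12 days), turned to −0.17 when scaled on the probes above the negative controls. In the 14q32 cluster (44, −0.19, 0.691) miR-299-5p and miR-433 (0.89 ± 0.28, adjusted p = 0.0467, 11 days) rose, and 1 member adjusted over the list alone. The calls of let-7e, miR-30d* and miR-433 were lost without any 1 of 14, 15 and 17 of the 24 arrays and that of miR-525-5p without replicate 2 at 24 h or replicate 3 at 72 h of 20 µM. Over the alternatives the adjusted p reached 0.953, 0.236, 0.92 and 0.508, from 0.0106, 0.0033, 0.00337 and 0.00495 for let-7e, miR-30d*, miR-433 and miR-525-5p. Scaling on the spike spots ended all 4 calls, and quantile normalization and the authors' values those of let-7e, miR-30d* and miR-433.

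The inflammation list (11 probes, median −0.05, camera adjusted p = 0.676) held 1 rise by either count, that of miR-21, beside miR-146b-5p (0.61 ± 0.28, adjusted p = 0.159). No member passed by either count in the ER stress list (25, 0.04, 0.342), where miR-204 had −0.26 ± 0.11, in the lipid and bile acid list (22, 0.03, 0.267), or in the hypoxia list (8, 0.05, 0.691), where miR-103a had 0.50 ± 0.42. The same was true of the miR-200 family (9, −0.13, 0.834), where miR-200b had 0.68 ± 0.30 and miR-200c −0.25 ± 0.09. It was also true of the miR-15, miR-16 and miR-503 family (10, −0.06, 0.691), where miR-497 had 0.53 ± 0.27, and of the miR-181 family (7, −0.21, 0.834), where miR-181a* had −0.56 ± 0.20. Among markers of other cells, the endothelium and fibroblast list (12, −0.11, 0.734) held 1 fall by either count, that of miR-126 (−0.42 ± 0.12, adjusted p = 0.0357, lower on 11 of 12 days). Its call was lost with normexp, in the authors' values, when scaled on the spike spots and without any 1 of 11 arrays, and its adjusted p went from 0.0033 to 0.222 over the alternatives. In the blood list (10, −0.17, 0.691) miR-451 had −0.38 ± 0.15, in the muscle and neuron list (13, −0.19, 0.791) miR-1 had −0.23 ± 0.11, and no member of either passed by either count. For the hepatocyte-enriched, p53, miR-30, miR-15 and inflammation lists the median was negative while camera pointed up.

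The single times asked when 20 µM CsA separated from DMSO (3 arrays against 3). At 72 h, 13 miRNAs rose and 0 fell. Of the 13, 10 lay above the negative controls in the mean over 36 arrays and 5 in that of DMSO at 72 h. The miRNA miR-4306 rose 25.7-fold (4.68 ± 1.13, adjusted p = 0.0328). Rises in log2 units, from a level below the negative controls, were 5.08 ± 0.94 for miR-4285 (adjusted p = 0.00404), 4.43 ± 0.98 for miR-3915 (adjusted p = 0.018) and 4.27 ± 1.00 for miR-3611 (adjusted p = 0.0252). Rises at 72 h were also measured for miR-3196 (3.09, adjusted p = 0.00316), miR-4279 (2.79, adjusted p = 0.00785), miR-149* (adjusted p = 0.0252) and miR-21 (3.40, adjusted p = 0.0397). The median of all probes at 72 h was −0.23. The count was 1 without replicate 3 of 20 µM, 7 without its replicate 1, and 5 without replicate 1 or 3 of DMSO. It was 39 with the scan day as a block (38 higher, 1 lower), and 909 scaled on the probes above the negative controls (19 higher, 890 lower). With normexp it was 3 and with the compared groups alone 60 higher and 6 lower, and without the 2 arrays at 24 h 44 higher and 2 lower. The call of miR-4285 was lost without replicate 3 of 20 µM (adjusted p = 0.056, the highest over its alternatives, from 0.000604). Those of miR-4306, miR-3915 and miR-3611 were lost with normexp (adjusted p = 0.213 each, the highest) and without replicate 1 or 3 of 20 µM or of DMSO, that of miR-3611 also without replicate 2 of DMSO, and that of miR-4306 after quantile normalization.

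At 48 h of 20 µM, miR-4279 alone rose, 7.12-fold (2.83 ± 0.57, adjusted p = 0.0356), with 65 miRNAs at an unadjusted p under 0.05, and the median of all probes at −0.23. Its call was lost without any 1 of the 6 arrays, with quantile normalization, in the authors' values and when scaled on the probes above the negative controls (adjusted p from 0.00308 to 0.268). The count was 6 with normexp, 14 with the scan day as a block, 34 with the compared groups alone and 4 without the 2 arrays at 24 h. At 12 h the smallest p belonged to miR-21* (2.05 ± 0.52) and miR-3178 (1.79 ± 0.47), with an adjusted p of 0.419 each, and miR-3687 (1.42 ± 0.45, adjusted p = 0.999). At 24 h it belonged to miR-3612 (−1.70), miR-3140-3p (−1.21) and miR-548l (1.08), with an adjusted p of 0.218. Limma placed 0 miRNAs past the threshold at 12 h (36 at an unadjusted p under 0.05) and 0 at 24 h (187), and with the scan day as a block 3 were lower at 24 h. Without replicate 1 or 2 of DMSO at 24 h, 37 or 60 passed at 24 h. Whether the effect at 72 h differed from that at 12 h was tested for each miRNA, and 0 passed in limma (7 at an unadjusted p under 0.05, smallest adjusted p = 1). The smallest p belonged to miR-542-5p (1.88 ± 0.57), miR-193b* (1.07) and miR-1183 (−0.79).

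Of the lists at single times, the overlap list had a median of 0.47 at 12 h (adjusted p = 4.84e-05, and adjusted p = 0.423 with an estimated correlation), 0.23 at 48 h (1.07e-05, and adjusted p = 0.522 with an estimated correlation) and 0.74 at 72 h (5.76e-07, and adjusted p = 0.296 with an estimated correlation). Its effect at 72 h exceeded that at 12 h by a median of 0.31 (adjusted p = 0.0126, and adjusted p = 0.889 with an estimated correlation). The miR-17-92 clusters had 0.45 at 12 h (adjusted p = 0.00156, and adjusted p = 0.75 with an estimated correlation) and 0.51 at 72 h (0.000956, and adjusted p = 0.792 with an estimated correlation). For the miR-23/27/24 clusters the medians were 0.33 at 12 h (adjusted p = 0.00156, and adjusted p = 0.423 with an estimated correlation) and 0.62 at 72 h (0.0141, and adjusted p = 0.792 with an estimated correlation). For the fibrosis list the median was 0.29 at 12 h (0.00156, and adjusted p = 0.423 with an estimated correlation). Medians at single times and between them were computed with the main scaling alone.

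The comparison of 3 µM CsA with DMSO asked for effects of the lower dose. Averaged over times, miR-3196 had a log2 change of 1.12 ± 0.26 (adjusted p = 0.246, 12 arrays against 12) and was higher on 12 of 12 scan days. miR-3611 had 1.84 ± 0.50 (adjusted p = 0.42, 12 days) and miR-1290 2.56 ± 0.70 (adjusted p = 0.42, 11 days). None of the 3 passed, and limma placed 0 miRNAs past the threshold, with 108 at an unadjusted p under 0.05. With the scan day as a block miR-3196 and miR-3611 passed. The call was also gained by miR-3196 after quantile normalization and without replicate 1 of 3 µM at 12 h, and by miR-1290 without replicate 1 of 3 µM at 24 h. Over the alternatives the adjusted p went from 0.0226 to 0.664 for miR-3196, from 0.0299 to 0.73 for miR-3611 and from 0.0331 to 0.73 for miR-1290. In all 9 passed with the scan day as a block and with quantile normalization 1, as did 1 without replicate 1 of 3 µM at 12 h or at 24 h. The overlap list had a median of 0.21, which turned negative with quantile normalization, in the authors' values and when scaled on the probes above the negative controls (lowest −0.20). Its camera adjusted p was 0.0434, and adjusted p = 0.949 with an estimated correlation. In it 0 members passed over all miRNAs and 1 adjusted over the list alone. The day median lay above 0 on 10 of 12 days, the adjusted p with the scan day as a block was 0.0335, and the call was lost without any 1 of 13 of the 24 arrays (adjusted p from 0.000138 to 0.963). The miR-17-92 clusters had 0.24 (adjusted p = 0.0565, and adjusted p = 0.949 with an estimated correlation). With the preset correlation, the only one tried there, they passed under 13 alternatives (adjusted p from 0.000621 to 0.963 over all), among them normexp, the stricter filter, scaling on the spike spots and the fit without the 2 arrays that stood apart. Their median turned negative when scaled on the probes above the negative controls (−0.17).

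At 72 h of 3 µM, miR-27b had 2.92 ± 0.83, miR-21 2.73 ± 0.85 and miR-92a 2.49 (adjusted p = 0.999 each). At 24 h miR-411* had 1.87, miR-2276 1.13 and miR-1284 0.95 (adjusted p = 0.133). The smallest p at 12 h belonged to miR-3178 (1.1), miR-2682 (−0.85) and miR-129-3p (−0.71), with an adjusted p of 0.999. At 48 h it belonged to miR-628-5p (−0.68), miRPlus-J376c* (−0.67) and miR-626 (−0.59), with an adjusted p of 0.99. Limma placed 0 miRNAs past the threshold at 12, 24, 48 and 72 h, with 11, 261, 21 and 46 at an unadjusted p under 0.05. At 24 h, where replicate 1 stood apart, quantile normalization gave 10 and the authors' values 31. There, 45, 48, 156 or 126 passed without replicate 1 or 2 of DMSO or replicate 2 or 3 of 3 µM. At 72 h 1 passed without replicate 2 of DMSO. The overlap list had 0.37 at 12 h (adjusted p = 1.23e-05, and adjusted p = 0.536 with an estimated correlation) and 0.24 at 48 h (0.00128, and adjusted p = 0.751 with an estimated correlation). The miR-17-92 clusters had 0.28 at 12 h (0.0377, and adjusted p = 0.729 with an estimated correlation) and 0.57 at 72 h (0.00154, and adjusted p = 0.671 with an estimated correlation).

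The doses themselves were compared by 20 against 3 µM averaged over times. Here miR-299-5p was 4.76-fold higher at 20 µM (2.25 ± 0.43, adjusted p = 0.011), miR-4279 3.45-fold (1.79 ± 0.28, adjusted p = 0.00104) and miR-149* 3.34-fold (1.74 ± 0.35, adjusted p = 0.0123). At 72 h the scaled log2 signal of miR-299-5p was 10.82 ± 0.60 (SD, n = 3) at 20 µM, 6.95 ± 1.71 at 3 µM and 7.74 ± 0.57 with DMSO. For miR-4279 it was 10.72 ± 0.17, 7.70 ± 1.18 and 7.93 ± 0.62. Replicate 3 of 3 µM at 72 h, an array with 298 spots not found, was the lowest of its group, at 5.188 for miR-299-5p and 6.502 for miR-4279. These 3 were the only miRNAs past the threshold (130 at an unadjusted p under 0.05). After quantile normalization 0 passed, with the compared groups alone 1, scaled on the spike spots 1, and with the scan day as a block 8, and miR-299-5p did not pass in the authors' values. The adjusted p reached 0.108 for miR-299-5p and miR-149* and 0.0539 for miR-4279, from 0.00125, 0.00147 and 6.62e-05. The count was 17 without replicate 2 of 3 µM at 24 h, 6 without replicate 1 of 20 µM or replicate 2 of 3 µM at 12 h, and 5 without replicate 3 of 3 µM at 24 h. In the overlap list 15 of 16 members had a positive estimate (median 0.26, camera adjusted p = 7.62e-06, and adjusted p = 0.488 with an estimated correlation), with no other scaling tried.

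In the solvent control, DMSO at 72 h was compared with 12 h (3 arrays against 3), where time and scan day cannot be told apart because every scan day held a single time. The miRNA miR-15a had −1.72 ± 0.58 and miR-1260 −3.40 ± 1.22, while miR-622 had 0.61 (adjusted p = 1 each). Limma placed 0 miRNAs past the threshold, with 37 at an unadjusted p under 0.05, and 2 passed in the authors' values. In the miR-17-92 clusters 0 of 19 probes had a positive estimate (median −0.77, camera adjusted p = 1.05e-06, and adjusted p = 0.408 with an estimated correlation). The p53 list had −0.21 (adjusted p = 0.0106, and adjusted p = 0.408 with an estimated correlation) and the miR-15, miR-16 and miR-503 family −0.23 (0.0181, and adjusted p = 0.441 with an estimated correlation), with no other scaling tried.

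**Figure D4:**
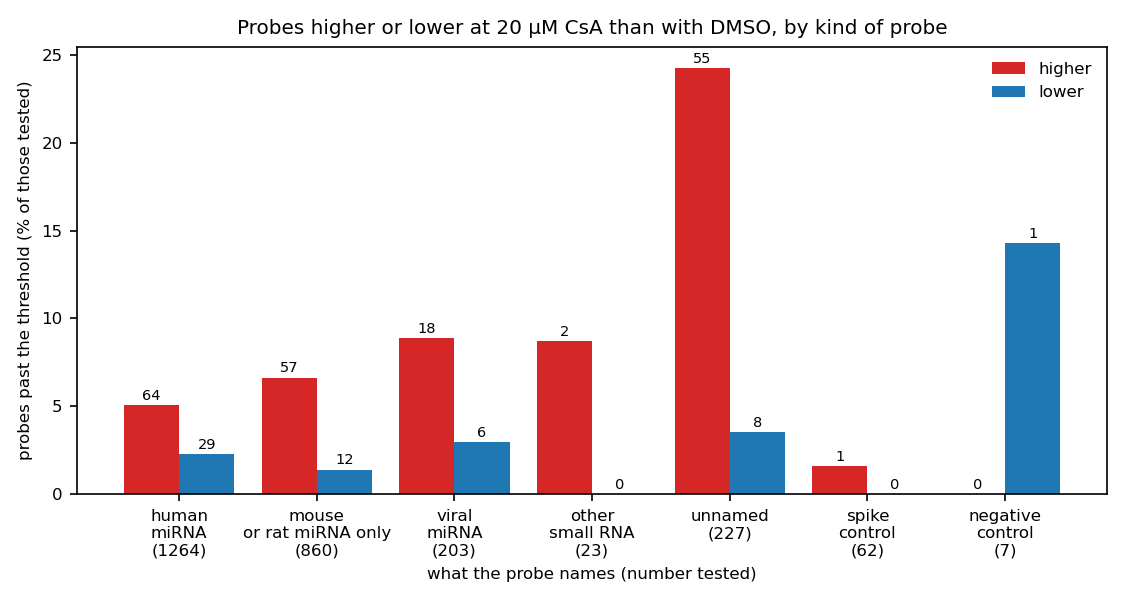
Percent of the tested probes (y axis) of each kind of probe (x axis) that were higher (red bars) or lower (blue bars) at 20 µM CsA than with DMSO averaged over times, adjusted within each kind, with the counts on the bars. Of the human miRNA probes 64 were higher and 29 lower, and of 203 probes that name only a viral miRNA 18 were higher and 6 lower.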

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

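The tests with other scalings and the test of the level of the fallen probes were chosen only after the results were seen. The tests on viral probes, scan days and other splits of the arrays were set beforehand.

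The effect of 20 µM CsA on the list of entries that overlap tRNA, U2 and other small RNAs differed between times. It was larger at 72 h than at 12 h by a median of 0.31 over 16 probes (camera adjusted p = 0.0126), a call that was lost with an estimated correlation (adjusted p = 0.889). No single miRNA passed this test in limma (7 at an unadjusted p under 0.05), and on other splits of the arrays up to 31 miRNAs did.

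Probes outside the human miRNAs entered the scaling in part, but not the tests of single human miRNAs. Some of these probes were higher at 20 µM CsA than with DMSO averaged over times as well, adjusted within each class and with the main scaling alone. Higher were 57 of 860 probes that name only a mouse or rat miRNA (12 lower), 18 of 203 that name only a viral miRNA (6 lower), 55 of 227 without a name (8 lower), 2 of 23 for other small RNAs (0 lower) and 1 of 62 spike controls (0 lower). Of the 7 negative control probes 0 were higher and 1 was lower. Whether the probes for mouse or rat miRNAs bound human counterparts was not tested, and the targets of the unnamed probes are not given in the sources used here.

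The rise of 64 miRNAs at 20 µM averaged over times was weighed against technical explanations. A shift common to the arrays of a scan day is excluded by the design, since each of the 12 days held 1 array of each dose, so the fit with the scan day as a block, in which 64 of 64 passed, left the estimates as they were and tests nothing further. Binding of RNA other than the named miRNA met the mark set for it beforehand. Of the viral probes 8.87 % (5.34 to 13.7 %, 95 % exact interval) rose when adjusted together with the human probes. Of the human ones 5.14 % did (Fisher's exact test, two-sided, p = 0.0474). The interval and this test take probes as independent, which probes of the same arrays are not. They therefore do not show that viral probes rose more often than human ones. The sample labels name no virus, so the rises of viral probes need not stem from the miRNAs they name. How many of the 64 rises have such a source cannot be told from these probes. Scaling on probes near background cannot be told apart from a rise of the named miRNAs, because with the spike control spots the median change of the 64 went from 1.30 (median SE 0.29) to 1.14 (0.31), with 64 of 64 estimates positive and 34 past the threshold, and scaled on the probes above the negative controls to 0.44 (0.29), with 49 of 64 positive, 24 past it and 23 past it in both. The latter scaling is set by 333 probes that include 41 of the 64. RNA breakdown, of which the list of overlapping entries was set beforehand as a sign, was not tested. Nor was the lower correlation of some DMSO arrays with the other arrays tested as a cause. An effect of the dose of CsA on the named miRNAs stays open.

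The fall of 29 miRNAs at 20 µM averaged over times was weighed in the same way. A shift between scan days is excluded by the same balance of the doses over the days. The mean level of 29 of 29 lay at or under the 95th percentile of the negative control spots, so their signal may hold little of the named miRNAs, and the 7 negative control probes had a median of −0.29 themselves (1 lower past the threshold, adjusted within that class), against −0.46 for the 29 and −0.15 for all human probes. Whether scaling on probes near background made these falls cannot be told apart from a real decrease, because with the spike control spots the median went from −0.46 (median SE 0.13) to −0.61 (0.24), 29 of 29 estimates stayed negative and 0 passed, while scaled on the probes above the negative controls it was −1.32 (0.32) and all 29 passed, among 1063 falls. A lower level of these miRNAs under CsA stays open as well.

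Other splits of the same arrays into groups of the same sizes were counted for every number of miRNAs past the threshold. For 20 µM averaged over times the real split gave 93 and the highest of the other splits 18 (1 of 100 as large). That makes chance unlikely without excluding it, since 1 of 100 is the smallest share these splits can give. The other splits also moved labels across the scan days of a time, while the real doses were balanced over them. For 20 against 3 µM the real split gave 3 and the highest other 0 (1 of 100), with the same limits. That count of 3 was itself 0 after quantile normalization. For 3 µM averaged over times (0 against 3) and for the effect at 72 h minus that at 12 h (0 against 31) the real count of 0 makes all 100 of 100 splits as large, so the splits decide nothing there. With the scan day as a block 9 miRNAs passed at 3 µM averaged over times, and splits were not counted for that fit. At a single time the 10 splits are too few for a share under 0.05. The real value and the highest other were 0 and 0, 0 and 1, 1 and 0, and 13 and 0 for 20 µM at 12, 24, 48 and 72 h, and 0 and 0, 0 and 274, 0 and 0, and 0 and 2 for 3 µM. For DMSO at 72 against 12 h they were 0 and 6. The split with 274 miRNAs belongs to 24 h of 3 µM, where 2 of the 6 arrays stood apart, and what lies behind it was not tested.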

How the results depend on the processing

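The negative control filter, the scaling on the probes above the negative controls, the scaling on the spike spots and the fit without the 2 arrays at 24 h were chosen after seeing the data. Signal over background limits most probes, since 1077 of 1264 lay at or below the negative controls. Of the 12 largest rises at 20 µM averaged over times, 11 kept their direction and passed without any single array and under every alternative that tested them (the stricter filter left out miR-1290 and miR-299-5p). Their size varied more, and the log2 change of miR-1290 ran from 2.15 to 3.92. Sign changes of values that passed in neither setting were counted as no change. The cause was not tested for any of the changes below, except that filters tested fewer probes. Scaling on another set of probes, by its construction, moves the log2 values of all probes of an array by the same amount.

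With normexp, 48 miRNAs passed at 20 µM averaged over times (46 higher, 2 lower, in place of 93), 6 at 48 h (in place of 1), 3 at 72 h (in place of 13), and 1 list at 20 µM (in place of 4) and 2 at 3 µM (in place of 1). The percentile over all non-control probes left 0 lists at 3 µM. Quantile normalization gave 10 miRNAs at 24 h of 3 µM and 1 at 3 µM averaged over times (both in place of 0). It gave 0 for 20 against 3 µM (in place of 3), 0 lists at either dose, and −0.74 for miR-34a at 20 µM averaged over times (in place of 0.02). The compared groups alone gave 145 at 20 µM averaged over times, 34 at 48 h, 66 at 72 h and 1 for 20 against 3 µM. The stricter filter left 2 lists at 20 µM and gave 2 at 3 µM, from 19 tested, and 2 miRNAs for 20 against 3 µM. Of 1275 probes without a filter, 90 passed at 20 µM averaged over times.

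With the scan day as a block, 236 passed at 20 µM averaged over times, 3 at 24 h (in place of 0), 14 at 48 h, 39 at 72 h, 9 at 3 µM averaged over times and 8 for 20 against 3 µM. The replicate block gave 97 at 20 µM averaged over times and 6 for 20 against 3 µM. Whether equal replicate numbers pair the samples is not shown by the correlations. The changes of equal numbers correlated above 0.1 in 13 of 24 pairs (median r 0.126) and those of equal scan days in 16 of 24 (0.267), and the 2 kinds of pair differed in 8 of the 24. The authors' values gave 0 at 48 h, 31 at 24 h of 3 µM, 2 for DMSO at 72 against 12 h (in place of 0), 1 list at 20 µM and 0 at 3 µM.

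The negative control filter gave 10 at 48 h, 36 at 72 h, 8 for 20 against 3 µM and 0 lists at either dose from 9 tested, and turned the test of the miR-17-92 clusters at 20 µM downward (median 0.35). Scaling on the probes above the negative controls gave 1087 at 20 µM averaged over times, 0 at 48 h, 909 at 72 h and 1 list at 20 µM, and at 20 µM averaged over times turned miR-34a to −0.84, miR-200a to −0.46 (in place of 0.40) and miR-525-5p to −0.17 (in place of 0.69). Scaling on the spike spots gave 34 at 20 µM averaged over times, 4 at 48 h, 1 for 20 against 3 µM and 2 lists at 3 µM. Without the 2 arrays at 24 h, 4 passed at 48 h, 46 at 72 h, 5 for 20 against 3 µM, 1 list at 20 µM and 2 at 3 µM.

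Leaving out each array in turn gave 51 to 141 miRNAs at 20 µM averaged over times (lowest without replicate 3 of 20 µM at 72 h, highest without replicate 2 of DMSO at 24 h) and 1 to 4 lists. It gave 0 to 1 miRNAs and 0 to 3 lists at 3 µM, and 3 to 17 miRNAs for 20 against 3 µM (highest without replicate 2 of 3 µM at 24 h). At single times it gave 0 to 60 at 24 h (highest without replicate 2 of DMSO), 0 at 48 h and 1 to 14 at 72 h of 20 µM (1 without its replicate 3). For 3 µM it gave 0 to 156 at 24 h (highest without its replicate 2) and 0 to 1 at 72 h (1 without replicate 2 of DMSO). It gave 0 throughout at 12 h of both doses, 48 h of 3 µM, DMSO at 72 against 12 h and the effect at 72 h minus that at 12 h. A lone pair of arrays was assumed to vary like the other groups.

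Of the values of single miRNAs, the scan day as a block brought 20 past the threshold and ended 0, while normexp ended 20, quantile normalization 22 and brought 8, the authors' values ended 20 and brought 7, and the spike spots ended 19. The scaling on the probes above the negative controls ended 8 and brought 38.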

Other observations

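Among the 23 probes for other small RNAs, whose single values were looked at only after the counts were seen, SNORD3@, the U3 small nucleolar RNA, rose by 2.10 ± 0.44 log2 units at 20 µM CsA averaged over times (SE, adjusted p = 0.00136 within its class). RNU1, the U1 small nuclear RNA, rose by 1.89 ± 0.50 (adjusted p = 0.00916). The 5S_rRNA probe had 1.86 ± 0.97 (adjusted p = 0.19) and RNU6-1 1.29 (adjusted p = 0.158), and the median of the class was 0.54. At 3 µM averaged over times SNORD3@ alone rose, by 1.51 ± 0.44 (adjusted p = 0.0466). Of the viral probes, 2 were picked after their values were seen. hsv2-miR-H7-3p had 1.65 ± 0.22 (adjusted p = 3.8e-05) and hsv1-miR-H6-3p 2.61 ± 0.47 (adjusted p = 0.000531) at 20 µM averaged over times, both adjusted together with the human probes. The values of these small RNA and viral probes were computed with the main scaling alone. Scaling on the probes above the negative controls would move them down with all other probes.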
